A study of Mus musculus with 10 samples.

How the data were processed

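Total RNA of 10 samples of mouse embryonic fibroblasts, 5 with a Zbtb4 knock-out and 5 wild type, was labelled with biotin and hybridised to one-colour Affymetrix arrays, per the labels. The table used holds the authors' deposited values, 1 column per array and 1 line per probe set, for 41345 probe sets. The deposited values are on a log2 scale, as judged from their range, and lie at similar levels on all arrays, with lower quartiles from 2.677 to 2.725 and upper quartiles from 5.831 to 5.96; how the authors summarised probes, subtracted background and normalised arrays is not given in the sources used here. A normalization that equalises arrays would hide a change in total RNA content, and probe-level noise cannot be separated from the spread between arrays. Nothing on signal over background came with the values, so the level below which a log2 value is background is not known.

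Probe sets were named through the platform annotation given with the table. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none, and those with several or none were left out. Symbols were checked through Entrez identifiers against a RefSeq gene table, in which 23328 were found, and 0 changed. For each gene the probe set with the highest mean over all 10 arrays was used, which left 22180 genes, 21098 of them with a single probe set and 1082 with more. Control probe sets cannot be recognised among the unnamed ones; they did not enter the main comparison, which uses named genes only, but may be part of the alternative that tests all probe sets singly. Gene order on chromosomes was taken from the RefSeq table, and coordinates are not used here because the sources do not name the array's genome build.

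Differences between genotypes, knock-out minus wild type, were fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, on the deposited log2 values without further normalization, filter or covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. A gene's value was also compared by an exact two-sided permutation test over the 252 ways to choose 5 of 10 arrays, which cannot give less than p = 0.00794. Before the data were examined, 29 gene lists were fixed from textbook knowledge; 28 had at least 5 measured members and were tested, and the list of Y-linked genes and Xist, with 4, was not. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, with camera at an estimated correlation, and with fry, whose directional test asks whether members move on balance one way and whose mixed test asks whether they differ in either direction. List scores per array were compared by the same exact permutation test. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.

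The genes named were set by a rule written before the data were examined. It takes Zbtb4, then up to 12 genes per direction that pass the threshold with groups of arrays that do not overlap, and, where fewer pass, fills each direction to 6 by the smallest p-values, reported as not passing. It passes over gene models without a proper symbol, small nucleolar and micro RNAs and olfactory and vomeronasal receptors. It adds up to 4 members with the smallest p-values of each gene list described and, whatever their values, Mad2l1, Trp53, Cdkn1a, Zbtb33, Zbtb38, Cdkn2a and Mki67. The lists whose members are named were picked after the list results were seen, as those with an unadjusted camera p under 0.1, those passing fry's mixed test, and the DNA methylation list. Trp53 and Ddx3y are not analysed here, since no probe set used carries their symbol alone.

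The scripts were tested on simulated data for the same comparison and the same 22180 genes, with 50 genes changed at each of 4 sizes. The share recovered was 12% at 1.25-fold, 88% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, with 6 unchanged genes called. With no change simulated, 0 genes and 0 lists were called, and a list shifted as a whole was called with an adjusted p of 6.51e-09. These simulated genes vary independently of one another and many change at once, which eases the adjusted threshold, so these shares do not carry over to data in which few genes change. Nor does the simulation show how camera behaves when genes of a list vary together between cultures.

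The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, averaging all probe sets of a gene, testing all probe sets singly, eBayes with trend and robust (for lists, camera with a variance trend), array weights, the replicate number as a block, the mean level of Y-linked genes as a covariate (3 of the 4 genes planned), other thresholds, an estimated correlation or fry for the lists, and leaving out each array in turn. The trend setting left fry unchanged, so its fry results repeat the main ones. The closing section gives the effect of the alternatives.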

Results

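Gene expression was measured in primary mouse embryonic fibroblasts (MEFs), connective tissue cells cultured from embryos, here taken from the skin of the back at mid-gestation. Total RNA of 10 samples was hybridised to one-colour Affymetrix arrays, with 5 arrays of Zbtb4 knock-out cells and 5 arrays of wild-type cells. Zbtb4 encodes a zinc finger protein that binds methylated CpG sites, and the comparison asked which transcripts depend on it. The deposited log2 expression values had similar levels on all arrays, with medians from 3.89 to 3.93. Any pair of arrays correlated with r between 0.989 and 0.994 across 22180 genes, which are not independent replicates, and no arrays held identical values. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.101. The labels number the arrays of each genotype from 1 to 5 without saying that they came from separate embryos, so p-values measure only the spread between these samples. Markers of sex, given at the end, show that each genotype holds samples of more than 1 embryo, and whether arrays of one sex are technical repeats is not known.

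Zbtb4 itself was lower in knock-out cells. Its one probe set, 17251728, gave a mean log2 value of 5.45 ± 0.27 (SD, n = 5) in the knock-out and 6.07 ± 0.11 (SD, n = 5) in the wild type. The difference was -0.62 with a standard error of 0.12 and a 95% interval from -0.88 to -0.36, so the signal was 1.54-fold lower. All 5 knock-out arrays, from 5.04 to 5.76, lay below all 5 wild-type arrays, from 5.94 to 6.23. The exact two-sided permutation test gave p = 0.00794, the smallest value that 5 against 5 arrays can give, while the limma adjusted p over all genes was 0.628. The labels do not say which part of the gene is deleted, and probes outside it would keep their signal, so this value does not measure how much intact transcript was left.

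No gene passed the threshold in either direction. Among 22180 genes, limma found 0 with an adjusted p under 0.05 and 0 under 0.1, and the smallest adjusted p was 0.2, for Thg1l. At an unadjusted p under 0.05 there were 1326 genes, 5.98% of those tested, where chance alone gives 1109. Of these, 720 were higher and 606 lower in knock-out cells. At an unadjusted p under 0.001 there were 22 genes, against 22.2 from chance. The 2 groups of arrays did not overlap for 219 genes, or 0.987%, where chance gives 0.794%. Only 23 genes differed by at least 1.5-fold in their means, 8 higher and 15 lower, and none by 2-fold. In simulated data of the same size, 88% of genes changed 1.5-fold and 94% of genes changed 2-fold were recovered, and 12% of those changed 1.25-fold. Many simulated genes changed at once, which eases the adjusted threshold, so a gene changed alone would be recovered less often.

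The genes with the smallest p-values are given as values that did not pass. Thg1l, the tRNA-histidine guanylyltransferase gene on chromosome 11, had a mean of 6.003 ± 0.12 (SD, n = 5) in knock-out cells and 5.26 ± 0.22 (SD, n = 5) in wild-type cells, a log2 difference of 0.74 with a standard error of 0.11. Without wild-type array 5, Thg1l alone passed the threshold, with an adjusted p of 0.0294 and a difference of 0.82. Cdh5, which encodes the endothelial adhesion molecule VE-cadherin, differed by 0.61 (adjusted p = 0.628), from 2.95 ± 0.13 in the wild type to 3.56 ± 0.22 in the knock-out (SD, n = 5 each), levels below the median of every array. Tnfrsf23, a receptor of the tumour necrosis factor family, differed by 0.45 (adjusted p = 0.628). Cd59a, an inhibitor of the complement membrane attack complex, differed by 0.64 and Tcp11l2 by 0.36, both with an adjusted p of 0.804. Ankub1, at 2.69 in wild-type cells and thus also below every array's median, differed by 0.56 (adjusted p = 0.804). The groups of arrays did not overlap for these genes, except for Cd59a.

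On the lower side, Tmem88, a membrane protein gene that lies 18 genes from Zbtb4 on chromosome 11, had the smallest p-value. Its mean was 6.39 ± 0.13 (SD, n = 5) in knock-out cells and 6.98 ± 0.16 (SD, n = 5) in wild-type cells, a log2 difference of -0.59 with a standard error of 0.093 and an adjusted p of 0.276. After Zbtb4 came Cluh, also on chromosome 11, which encodes a protein binding mRNAs of mitochondrial proteins and differed by -0.34. Adam23, a member of the disintegrin family, differed by -0.41, and Jpt2 by -0.32. Tfap2b, a transcription factor gene of the AP-2 family, was at 2.77 ± 0.11 in knock-out cells and 3.30 ± 0.31 in wild-type cells (SD, n = 5 each), a difference of -0.54 at levels below every array's median. Cluh, Adam23, Jpt2 and Tfap2b each had an adjusted p of 0.804, and their groups of arrays did not overlap.

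**Figure D1:**
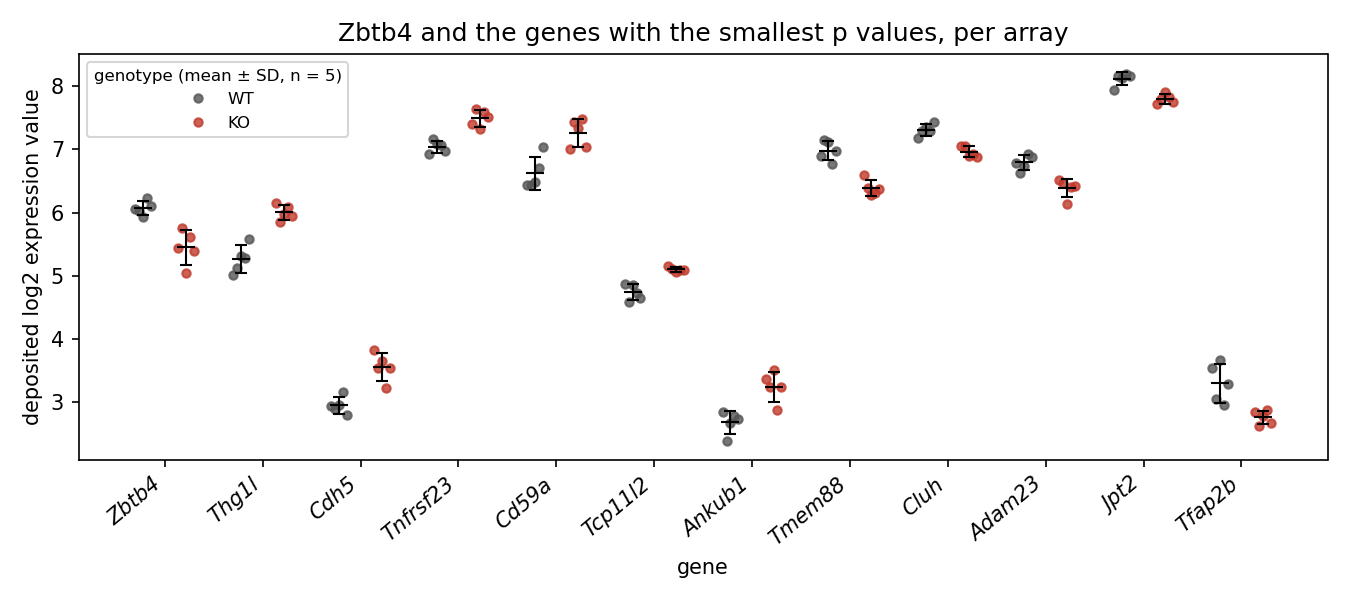
Deposited log2 expression values of Zbtb4 and of the genes with the smallest p-values in each direction; each point is 1 array, and bars give the mean and SD of 5 wild-type (grey) or 5 knock-out (red) arrays. Knock-out arrays of Zbtb4 sit between 5.04 and 5.76 and wild-type arrays between 5.94 and 6.23, while Cd59a overlaps between genotypes.

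**Figure D2:**
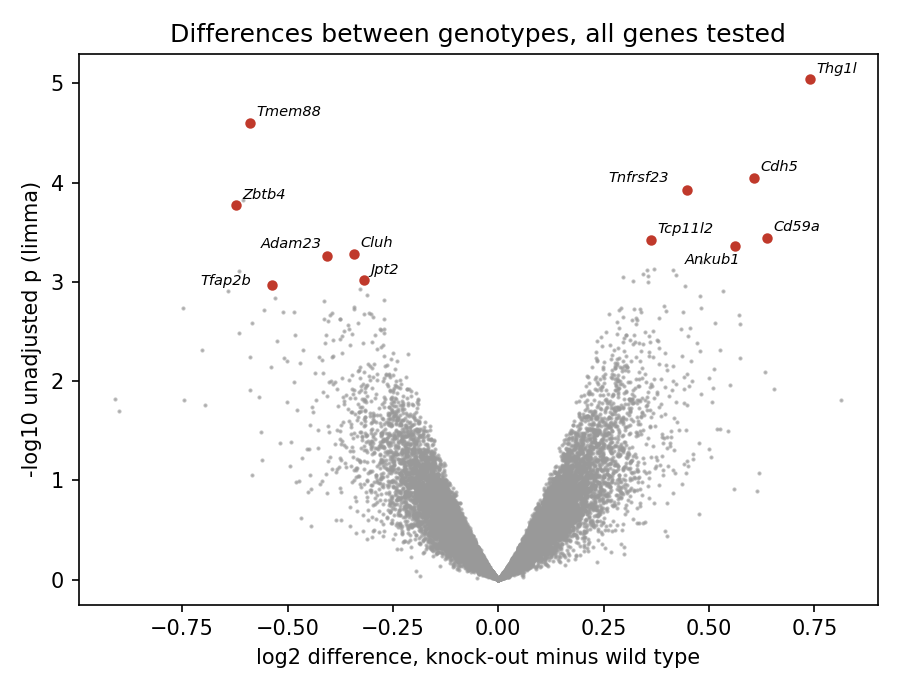
Log2 difference, knock-out minus wild type, on the x axis and -log10 of the unadjusted limma p-value on the y axis for 22180 genes (grey points), with Zbtb4 and the genes with the smallest p-values in red. The largest differences stay within 1 log2 unit either way, and none of the genes shown passed an adjusted p of 0.05.

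Gene lists fixed before the data were examined were compared with all other genes by camera. Of 28 lists tested, 5 were lower and 1 was higher in knock-out cells at the preset correlation between genes of 0.01. None of the 6 calls held with an estimated correlation, where the smallest adjusted p was 0.559, and none of the lists passed fry's directional test. The estimated correlation was 0.68 for G2/M, 0.67 for sterol synthesis, 0.51 for G1/S and 0.48 for spindle checkpoint genes. It was 0.44 for the Atf4 list and 0.21 for smooth muscle genes. All lie well above the preset of 0.01, so the 6 calls and their small p-values rest on that preset. For each list, a score was also computed for every array as the members' mean deviation from their means over the 10 arrays, and no list passed an exact permutation test of these scores after adjustment. The arrays of the 2 genotypes overlapped in the scores of all 6 lists.

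Genes of cell division had mostly lower means on the knock-out arrays, a difference that did not pass the permutation test of list scores. Of 27 measured genes of G2/M phase and mitosis, 26 had a lower mean and 1 a higher mean, with a median log2 difference of -0.20 (camera, adjusted p = 8.97e-10; adjusted p = 0.559 with an estimated correlation). Their score was -0.094 ± 0.194 (SD, n = 5) in knock-out and 0.094 ± 0.137 (SD, n = 5) in wild-type arrays (exact permutation p = 0.119, adjusted 0.586). Cdc25c, the phosphatase that activates the mitotic kinase Cdk1, differed by -0.41 and was the only member to pass when adjusted over the list alone (limma adjusted p = 0.0422); no member passed over all genes. The mitotic kinesin gene Kif23 differed by -0.31, the spindle assembly factor gene Tpx2 by -0.25 and the cyclin gene Ccnb2 by -0.26. The proliferation marker Mki67 was at 8.29 ± 0.19 (SD, n = 5) in knock-out and 8.49 ± 0.22 (SD, n = 5) in wild-type cells (limma adjusted p = 0.842), a difference of -0.20 that came to -0.12 without knock-out array 4.

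The spindle assembly checkpoint, which delays anaphase until chromosomes are attached, was represented by 20 genes, of which 19 had a lower mean. Their median log2 difference was -0.18 (camera, adjusted p = 3.77e-06; adjusted p = 0.559 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The kinase gene Aurkb differed by -0.31, Trip13 by -0.18, Zw10 by -0.17 and the kinase gene Ttk by -0.38. Mad2l1, the checkpoint protein that inhibits Cdc20, was at 6.99 ± 0.29 in knock-out cells and 7.19 ± 0.17 in wild-type cells (SD, n = 5 each; limma adjusted p = 0.848). One array moved the median by over 1.5 times, to -0.27 without knock-out array 1 and to -0.12 without knock-out array 4; Mad2l1 then differed by -0.31 and -0.12 and Ttk by -0.56 and -0.23.

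Of 28 genes of G1/S transition and DNA replication, 25 had a lower mean, with a median log2 difference of -0.14 (camera, adjusted p = 3.33e-05; adjusted p = 0.592 with an estimated correlation). The replication licensing factor gene Cdt1 differed by -0.26, the DNA polymerase gene Pola1 by -0.34, Gins1 by -0.21 and the helicase subunit gene Mcm5 by -0.28. No member passed, over all genes or adjusted over the list alone. In all 3 lists wild-type array 5 had the lowest score of its genotype, -0.11 to -0.15, and knock-out array 4 the lowest of all arrays, -0.29 to -0.37.

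Genes of sterol synthesis were lower as a group, with 15 of 16 means lower and a median log2 difference of -0.15 (camera, adjusted p = 0.00106; adjusted p = 0.645 with an estimated correlation). Lss, which forms lanosterol, differed by -0.40, the squalene epoxidase gene Sqle by -0.19, Dhcr7 by -0.22 and the sterol sensor gene Insig1 by -0.31. No member passed, over all genes or adjusted over the list alone. The call depended on knock-out array 2, whose score was -0.48 against -0.24 to 0.21 on the other knock-out arrays. Without that array the median was -0.045 and the adjusted p 0.185, and Lss differed by -0.25, Dhcr7 by -0.10 and Insig1 by -0.13; Sqle differed by -0.12 without knock-out array 3.

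Targets of Atf4, a transcription factor of the amino acid stress response, together with genes of the unfolded protein response had 16 of 19 means lower, with a median log2 difference of -0.10 (camera, adjusted p = 0.00794; adjusted p = 0.645 with an estimated correlation). The serine synthesis gene Psat1 differed by -0.22, Shmt2 by -0.22, the asparagine synthetase gene Asns by -0.21 and Trib3 by -0.42, and none passed over all genes or adjusted over the list alone. The call was lost without knock-out array 2 (adjusted p = 0.0877), 4 (0.0887) or 5 (0.0956) or wild-type array 2 (0.0579), with medians of -0.051, -0.066, -0.067 and -0.071, and Asns differed by -0.11 without knock-out array 2. Without knock-out array 1 the median was -0.17.

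Smooth muscle and myofibroblast genes had higher means on the knock-out arrays. All 15 measured members had a higher mean in knock-out cells, with a median log2 difference of 0.077 (camera, adjusted p = 0.00288; adjusted p = 0.559 with an estimated correlation). Calponin, encoded by Cnn1, had a mean of 10.83 ± 0.23 (SD, n = 5) in knock-out and 10.46 ± 0.27 (SD, n = 5) in wild-type cells, a difference of 0.37. The myosin light chain gene Myl9 differed by 0.16, the tropomyosin gene Tpm2 by 0.12 and the smooth muscle myosin gene Myh11 by 0.30, or 0.17 without knock-out array 3. None passed, over all genes or adjusted over the list alone. The list score was 0.060 ± 0.063 in knock-out and -0.060 ± 0.092 in wild-type arrays (SD, n = 5 each; exact permutation p = 0.0556, adjusted 0.519), and without knock-out array 5 the median difference was 0.12.

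**Figure D3:**
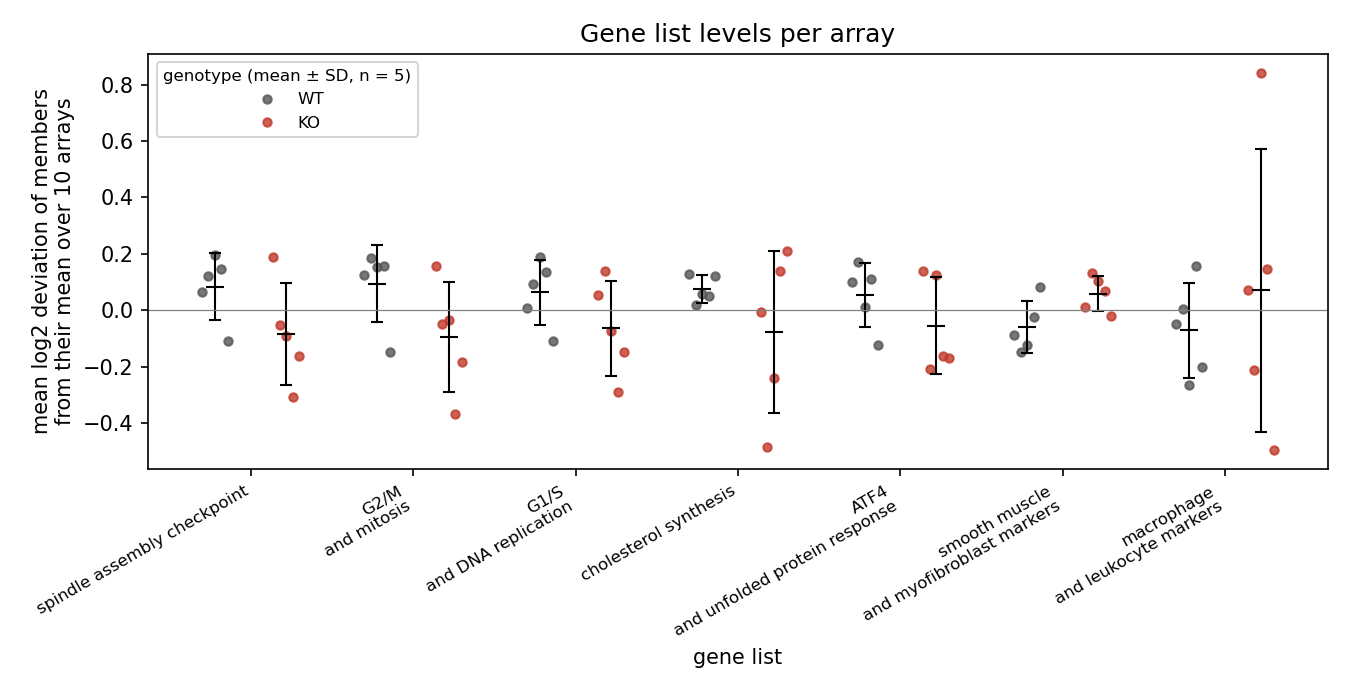
Gene list levels per array, on the y axis as the members' mean log2 deviation from their means over 10 arrays, for the 6 lists that passed camera at the preset correlation and for macrophage and leukocyte markers. Each point is 1 array, and bars give mean and SD of 5 wild-type (grey) or 5 knock-out (red) arrays; the genotypes overlap in every list, and knock-out array 3 stands at 0.84 for leukocyte markers.

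Targets of p53 and the cell cycle inhibitors linked to senescence did not pass. Of 23 measured p53 targets, 16 had a higher mean, with a median log2 difference of 0.033 (camera, adjusted p = 0.176; adjusted p = 0.756 with an estimated correlation), and the list passed only without wild-type array 5 (median 0.092, adjusted p = 0.0126), while the median was 0.0063 without wild-type array 4. Cdkn1a, which encodes the inhibitor p21, was at 11.18 ± 0.11 in knock-out and 10.96 ± 0.15 in wild-type cells (SD, n = 5 each), a difference of 0.23 (limma adjusted p = 0.821). Among other targets, Rrm2b differed by 0.17, Bbc3 by -0.18 and Pmaip1 by 0.43, which ran from 0.26 to 0.65 with single arrays left out. Cdkn2a, the locus of p16 and Arf, differed by 0.10 (adjusted p = 0.904), and by 0.047 to 0.20 with single arrays left out. Among 22 senescence and secretory genes, 12 were higher and 10 lower, and the median of 0.027 and the mean of -0.022 differed in sign (adjusted p = 0.992). Trp53, which was to be reported whatever its value, has no probe set that carries its symbol alone and is not analysed here.

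Zbtb33 and Zbtb38, the other methyl-CpG binding proteins of the same family, differed by -0.024 (adjusted p = 0.977) and -0.051 (adjusted p = 0.941); the sign of Zbtb33 turned under quantile normalization, to 0.0099. Readers, writers and erasers of DNA methylation were mixed, with 8 of 17 higher and 9 lower and a median of -0.024 (camera, adjusted p = 0.453), which turned to 0.0019 under quantile normalization. The glycosylase gene Mbd4 differed by -0.17, the methyltransferase genes Dnmt3b and Dnmt3a by -0.21 and 0.17, and Uhrf1 by -0.18; Dnmt3a came to 0.094 without wild-type array 5 and Uhrf1 to -0.10 without knock-out array 4. Of 27 germline genes that DNA methylation keeps silent in somatic cells, 20 had a higher mean, with a median of 0.047 (camera, adjusted p = 0.180; adjusted p = 0.559 with an estimated correlation). Their members with the smallest p-values, Rpl10l, Mov10l1, Asz1 and Dpep3, had knock-out means from 2.04 to 3.29, below every array's median, and differed by 0.15, 0.18, 0.16 and 0.14. Without a single array, the median of this list came to 0.031 (wild-type array 2), Rpl10l to 0.097 (knock-out array 4) and Dpep3 to 0.033 (knock-out array 3). Imprinted genes numbered 13 higher and 20 lower, with a median of -0.035 (adjusted p = 0.666). No member of these 3 lists passed, over all genes or adjusted over the list alone.

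Genes beside Zbtb4 on chromosome 11 went both ways. Of 39 measured, 22 had a higher and 17 a lower mean, and camera gave an adjusted p of 0.696, with a median of 0.013 and a mean of -0.012 that differed in sign. The mixed test of fry, which asks whether members differ in either direction, gave an adjusted p of 0.000402. Tmem88 was the only member to pass when adjusted over the list alone (limma adjusted p = 0.00097). Without Tmem88, the same mixed test of the other 38 members gave an unadjusted p of 0.0466. Fxr2 differed by 0.18, Gps2 by -0.16 and Phf23 by 0.16.

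Markers of other cell types were examined because MEF cultures can hold other cells. Endothelial markers had 12 of 18 means higher (camera, adjusted p = 0.243) and an adjusted p of 0.0399 in fry's mixed test. Cdh5 was the only member to pass adjusted over the list alone (limma adjusted p = 0.0016), and without Cdh5 the mixed test of the other 17 members gave an unadjusted p of 0.446. Esam differed by 0.18, Robo4 by 0.16, or 0.098 without wild-type array 1, and Kdr by -0.19. This mixed call was lost in 11 of 18 other settings, 7 of them with a single array left out, and its adjusted p-values reached 0.812 when the dimmest 40% of genes, Cdh5 among them, were left out. Macrophage and leukocyte markers had 17 of 19 means higher and a median of 0.18 but did not pass (camera, adjusted p = 0.0597; adjusted p = 0.757 with an estimated correlation), although the list passed in 10 of 18 other settings. Their score was 0.84 on knock-out array 3 and -0.49 on knock-out array 5, against -0.27 to 0.16 in the wild type, and without array 3 the median turned to -0.049. Csf1r differed by 0.33, Cd53 by 0.33, Adgre1 by 0.26 and Itgam by 0.20, with adjusted p-values from 0.830 to 0.853; they came to 0.19, 0.13, 0.14 and 0.069 at the least with single arrays left out. Of 8 erythroid genes, 6 were higher (camera, adjusted p = 0.122), and their scores did not overlap between genotypes (exact permutation p = 0.00794, adjusted 0.222). The 2 groups of scores nearly touched, with knock-out array 4 at -0.0196 and wild-type array 4 at -0.0202. The globin genes Hba-x and Hbb-bh1 differed by 0.22 and 0.23 at knock-out means of 2.40 and 2.50. Slc4a1 differed by 0.28 and Epb42 by -0.14, or -0.063 without wild-type array 2.

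Adipocyte markers had 12 of 15 means lower, with a median of -0.077 (adjusted p = 0.122) that ran from -0.094 to -0.042 with single arrays left out. Scd1 differed by -0.27, Fasn by -0.17, Dgat2 by -0.20 and Fabp4 by 0.36; without a single array, Scd1 came to -0.14 (knock-out array 2), Fasn to -0.11 (the same array), Dgat2 to -0.13 (wild-type array 3) and Fabp4 to 0.16 (wild-type array 4). Immediate early genes had 14 of 17 means lower, with a median of -0.12 (adjusted p = 0.0597); the list passed in 9 of 18 other settings, down to an adjusted p of 0.0084 without knock-out array 1, but had an adjusted p of 0.559 with an estimated correlation, and its median was -0.063 without wild-type array 5. Among its members, Nr4a1 differed by -0.30, Ier2 by -0.24, Dusp1 by 0.27 and Jun by -0.19, which came to -0.18, -0.18, 0.17 and -0.12 at the least with single arrays left out. Interferon-stimulated genes had 17 of 27 means higher, with a median of 0.033 (adjusted p = 0.122) that ran from 0.0021 to 0.076 with single arrays left out. The list passed in 3 of 18 other settings, with adjusted p-values of 0.00437 without the dimmest 40% of genes, 0.037 without knock-out array 2 and 0.0363 without wild-type array 2, but it had an adjusted p of 0.578 with an estimated correlation. Ifit3 differed by 0.36, Xaf1 by 0.32, Tap1 by 0.14 and Dhx58 by 0.14. Of these, Xaf1 lies 82 genes from Zbtb4 on chromosome 11. Keratinocyte and epithelial markers had a median of 0.065 (adjusted p = 0.313), or 0.022 without knock-out array 2, skeletal muscle markers 0.039 (0.358) and cartilage and bone markers 0.060 (0.472). Medians were -0.0098 for cytosolic ribosomal proteins (adjusted p = 0.547), 0.0068 for Hox genes (0.684), 0.013 for hypoxia and glycolysis (0.684) and -0.0043 for the fibroblast extracellular matrix (0.992), and the sign for Hox genes turned when arrays were centred on their medians. For 3 further lists the median and the direction of the test differed in sign, namely targets of NRF2 (median -0.011, adjusted p = 0.666), targets of TGF-beta and BMP (-0.014, 0.760) and neuronal and glial markers (-0.017, 0.893), and the medians of the NRF2 and TGF-beta lists turned positive under quantile normalization. No member of the lists in this group passed, over all genes or adjusted over the list alone.

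Markers of sex divided the arrays of both genotypes alike. Xist, expressed from the inactive X chromosome, lay above 10 on knock-out and wild-type arrays 2, 4 and 5 and between 2.99 and 4.50 on arrays 1 and 3 of both genotypes. The Y-linked gene Eif2s3y lay between 6.83 and 7.17 on arrays 1 and 3 and between 2.33 and 2.60 on the others, and Kdm5d and Uty divided the arrays in the same way.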

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

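The splits of the arrays for genes passing the adjusted threshold and for the G2/M score, the counts among splits balanced for sex, the test without knock-out array 4 and the correlation of G2/M with smooth muscle scores were chosen after the results they bear on had been seen.

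A single array stood apart from the other 4 of its genotype in 7 of 214 groups tested by Dixon's criterion, where chance gives about 1 in 20, or 10.7. Wild-type array 5 accounts for 4 of them: Mki67 was at 8.10 there against 8.56 to 8.64 on the other wild-type arrays, and Ttk at 6.29 against 6.70 to 6.82. The G2/M score of that array was -0.147 against 0.124 to 0.186, and its NRF2 score 0.173 against -0.0704 to -0.0133. Wild-type array 1 gave 7.93 for Jpt2 against 8.12 to 8.18. On knock-out array 3, Dpep3 was at 3.70 against 3.15 to 3.27, and the score of the fibroblast extracellular matrix was -0.139 against 0.0118 to 0.0478. The chance figure of 10.7 takes the groups as independent, but Mki67 is itself part of the G2/M score. Most genes tested were also picked by small p-values, so 7 against 10.7 does not show that outliers were no more common than chance gives.

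Splits of the 10 arrays into 5 and 5 were counted, 100 drawn from 126 and including the real one. For genes past the adjusted threshold they decide nothing, since with the real count at 0 all 100 splits must give at least as many; the highest other count was 3. At an unadjusted p under 0.05, 14 of the 100 splits gave as many genes as the real 1326, with up to 1937 in another, so chance could not be excluded. For gene lists passing camera at the preset correlation, 47 of the 100 splits gave as many as the real 6, with up to 13 in another, so chance could not be excluded there either. These splits were drawn without regard to sex, for which the genotypes are balanced. Among the 54 splits balanced in the same way, the real one included, 5 gave as many genes, with up to 1497 in another, and 25 gave as many lists, with up to 12 in another. A split that mixes genotypes can thus call more lists than the genotypes do, which points to gene groups that vary together between arrays whatever their genotype.

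The lower level of cell division genes in knock-out cells rests on a score difference of -0.189 for G2/M genes. Of 100 splits, 11 gave a difference as large in size, with 0.247 as the largest of the others, and so did 5 of the 54 balanced for sex, so chance could not be excluded. Knock-out array 4 alone does not account for all of it, since 64.1% of the difference was left without that array (-0.121). A growth state that differs between cultures whatever their genotype remains open: within genotypes, G2/M and smooth muscle scores correlated with r = -0.426 (permutation p = 0.22) and rho = -0.321 (permutation p = 0.383) over 10 arrays, but r was 0.02 without knock-out array 4 and wild-type array 5, so the relation rests on those arrays. An effect of the genotype itself stays open as well, and the 10 arrays do not decide between them.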

How the results depend on the processing

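Alternatives were set before the data were examined. No gene passed in any of them, except Thg1l without wild-type array 5 (adjusted p = 0.0294; range over its settings 0.0294 to 0.834), so that genes higher in knock-out numbered 0 to 1 when single arrays were left out. Zbtb4 stayed lower, from -0.70 to -0.52, with adjusted p-values from 0.296 to 0.951. Of 1486 recomputed values of 79 genes, 6 changed sign, all of Zbtb33 and Zbtb38. The eBayes trend, the replicate block, leaving out dim genes and testing probe sets singly cannot change a gene's difference. Averaging cannot change it for a gene with a single probe set, and Zbtb4 gave -0.62 in each of these settings. Most of the 79 genes were also picked by small p-values, so the few sign changes say little about robustness. The lists of G2/M, spindle checkpoint, G1/S and smooth muscle genes passed camera at the preset correlation in every setting in which lists were recomputed, with adjusted p-values up to 0.000102, 0.0023, 0.0255 and 0.0374. The cause of the changes below was not tested, except that fewer arrays or genes entered where these were left out; signal over background is not known, which limits what can be said of dim genes, and genes among the dimmest 40% have no value where these are left out.

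Lists higher in knock-out numbered 0 and lists lower 0 with an estimated correlation, and 0 and 0 with fry's directional test. Lists higher numbered 2 with arrays centred on the median, 2 with the variance trend, 2 with the Y-linked level as a covariate, 3 without the dimmest 40% of genes, and 1 to 4 with single arrays left out; the lists added were macrophage markers, interferon-stimulated genes, NRF2 or p53 targets. Lists lower numbered 4 to 6 with single arrays left out and 6 with probe sets averaged, the variance trend, array weights or the Y-linked covariate; the list added was that of immediate early genes. Of 502 list values, 5 lost and 24 gained a call; none passed with an estimated correlation in any setting. With single arrays left out, 30 of 79 genes and 26 of 28 list medians moved by over 1.5 times or changed sign. The labels do not say that shared replicate numbers pair the arrays; deviations of same-numbered arrays correlated with r from -0.0455 to 0.165 and 3 arrays correlated best with their own number. Markers of sex agreed in all 5 numbers, so a pairing is not excluded. With the replicate number as a block, 0 genes passed (smallest adjusted p = 0.649), and lists higher numbered 2 and lists lower 6.

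Medians changed sign in 41 list values, none of them of the 6 lists called with all arrays. Changes of direction were first counted by camera's direction. After the output was seen, they were counted by the sign of the median, the planned measure, which raised the number. The variance trend and the replicate block cannot change a median. Under quantile normalization Zbtb33 gave 0.0099 and the lists of DNA methylation 0.0019, TGF-beta 0.0063 and NRF2 0.0029. With arrays centred on the median, Hox genes gave -0.0059. Without the dimmest 40% of genes, senescence gave -0.023, endothelial markers -0.070 and neuronal markers 0.041. With probe sets averaged, the extracellular matrix gave 0.0012. With array weights, Zbtb33 gave 0.0032, hypoxia -0.0099 and NRF2 0.0023. With single arrays left out, values ran from -0.056 to 0.018 for Zbtb33 and from -0.11 to 0.0092 for Zbtb38. List medians then ran from -0.026 to 0.025 for genes beside Zbtb4, -0.020 to 0.045 for Hox genes, -0.090 to 0.021 for TGF-beta, -0.015 to 0.054 for hypoxia, -0.044 to 0.032 for neuronal markers, -0.070 to 0.094 for NRF2, -0.028 to 0.0081 for the extracellular matrix, -0.049 to 0.29 for macrophage markers, -0.0031 to 0.045 for senescence, -0.042 to 0.079 for skeletal muscle, -0.011 to 0.072 for cartilage and bone, -0.068 to 0.0089 for imprinted genes and -0.050 to 0.0092 for DNA methylation.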

Other observations

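The window of 400 genes around Zbtb4, the comparison of shares in it and the count of genes lower there were chosen after the positions had been seen, as were the splits for nearby genes, for mixed tests and balanced for sex and the other windows.

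Among the 28 lists, scores spread most between arrays of one genotype for macrophage and leukocyte markers (pooled SD 0.373, with a difference between genotypes of 0.142) and sterol synthesis (SD 0.205, difference -0.151). For G2/M genes (SD 0.168, difference -0.189) and smooth muscle genes (SD 0.079, difference 0.119) the spread was smaller, and below the size of the difference. In 22 of the 28 lists the SD was above the size of the difference. Among these were the called lists of sterol synthesis, G1/S (SD 0.145, difference -0.127) and Atf4 (SD 0.146, difference -0.108). Knock-out array 2 had the lowest score for sterol synthesis, -0.48, and the highest for targets of TGF-beta and BMP, 0.33. Knock-out array 5 had the highest score for skeletal muscle markers, 0.30, and for cartilage and bone markers, 0.20.

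Several of the genes with the smallest p-values lie on chromosome 11, which carries Zbtb4: Thg1l, Tmem88, Cluh and Zbtb4 itself. Among 1648 other genes of that chromosome, 31 (1.88%) had an unadjusted p under 0.01, and 4 of 100 splits gave as many, with 42 as the highest of the others, as did 2 of the 54 splits balanced for sex. Although 4 of 100 is under the 5% level, the count includes Thg1l, Tmem88 and Cluh, which had been picked out by their p-values. Chromosome 12 also had a higher share (2.14%), so chance is not excluded. Limma's fry mixed test of the whole of chromosome 11 gave the smallest p of all chromosomes, 0.0134, as low in 4 of 100 splits. Its adjusted p over all chromosomes was 0.295. Of the 800 genes nearest to Zbtb4, 400 on each side, 21 (2.62%) had such a p, against 221 of 20340 (1.09%) on other chromosomes (Fisher exact p = 0.000455) and 10 of 848 (1.18%) farther away on chromosome 11 (Fisher exact p = 0.0443). The share was 2% in the nearest 50 genes on each side (Fisher exact p = 0.298), 4% in 100 (p = 0.00187) and 3.5% in 200 (p = 0.000201).

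DNA of another strain, carried along with the targeted allele, is a candidate explanation that a higher share near Zbtb4 would fit. The window test came out at Fisher exact p = 0.000455. Of 100 splits, 2 gave as many nearby genes as the real 21, the real one included. Neither tests the explanation, since the window was set after the positions were seen and takes in Thg1l, 375 genes away. Fisher's test also treats genes of the same arrays as independent. In the nearest 50 genes on each side, Fisher's exact test gave p = 0.298. For the list of genes beside Zbtb4, the fry mixed call held in all 18 other settings (limma adjusted p up to 0.0202). All of these settings kept Tmem88, and the trend setting only repeats the main fry test. No other split gave a fry mixed p as low as 1.43e-05 (lowest other 0.00478). Without Tmem88, however, the other 38 members gave a fry mixed p of 0.0466, as low in 8 of 100 splits. Whether such DNA would act on expression or on the match of probes to transcripts is open: 13 of the 21 nearby genes were lower and 8 higher in knock-out cells, and probe sequences and strain genotypes were not used here. Effects of losing Zbtb4 on its neighbours stay possible too. Besides Thg1l, Tmem88 and Cluh, Ttc1 (log2 difference 0.26), B9d1 (0.37), Tvp23b (0.35), Ttc19 (-0.28) and Med11 (-0.28) had groups of arrays that did not overlap; these were named after their values were seen, and all had adjusted p-values from 0.2 to 0.821.

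Leukocyte genes stood high on knock-out array 3. Of 19 genes of the macrophage and leukocyte list, 17 had their highest value there, among them Lyz2 (8.41, against 5.62 to 7.68 on the other arrays) and Tyrobp (7.49, against 4.83 to 6.31). A further list of leukocyte genes, sharing none with the first, was written before its values were looked at, and 57.1% of its 28 measured genes (16) were highest on that array, where chance gives 10%. A general shift of the array is argued against, since 11.4% of all genes were highest there. More leukocytes in that culture, the explanation that the further list tested, may account for the pattern; no biological explanation by genotype was tested, as 1 array of 5 does not separate the genotypes.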
